A study of Homo sapiens with 22 samples.

How the data were processed

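Gene expression was measured in IMR-90 cells, a strain of human lung fibroblasts with a limited lifespan in culture, after transfection with an siRNA to DNMT1, to MAD2 or to pRb, or with an siRNA to GFP as the negative control. Per the labels' protocols, RNA was extracted with Trizol and columns, labelled by a low-input amplification kit with Cy3 or Cy5, and hybridised to Agilent whole-genome arrays that carry 2 channels each. The 22 deposited samples are single channels of 11 arrays on 3 slides. Each slide holds 1 experiment with all 4 siRNAs, so slide, scan and experiment are the same division of the samples.

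Per the file headers, the deposited scanner files give processed signals, which are intensities on a linear scale made with Agilent Feature Extraction 9.5.1. Per the same headers, this software had subtracted the background, removed a spatial trend and normalized the dyes within each array by a linear step followed by a LOWESS step. The deposited series table holds log2 values that had been made alike between the samples: its 22 columns have medians near 6.42, and each column correlated best with its own sample's scanner values (Pearson r from 0.990 to 0.9998 across probes). This table served only as an alternative, and 0 of its columns of per-sample values were left unused.

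From the 45015 spots per array, the 43376 that are not controls were used, spots that the scanner software marked as non-uniform or as population outliers were left out, and spots of 1 probe were averaged to give 41000 probes. Processed signals were put on the log2 scale and each sample's 75th percentile was subtracted. Samples of an extract (1 siRNA in 1 experiment) share a source name and differ in dye. They were taken as 2 labellings of 1 extract, which correlated at r from 0.974 to 0.997, and counted as 1 replicate. A dye effect per probe, the mean Cy5 minus Cy3 difference over the 10 extracts with both dyes split equally between the dyes, was removed before the dyes were averaged. This also places the siGFP extract of experiment 3 (Cy5 alone) and the siMAD extract of experiment 3 (Cy3 alone) on the common scale. The result is 12 extracts, 3 per siRNA. A probe was kept if it was well above background in every sample of at least 1 siRNA, which left 23805 probes.

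Gene names came from the platform annotation table, in which 29341 probes have 1 gene symbol, 33 have several and 11626 are not named. The symbols were updated through the gene identifiers to the RefSeq gene table of assembly GRCh38.p14, where 29298 named probes matched. Probes with several symbols were not named. Of the kept probes of a gene, the 1 with the highest mean was used, which gave 12357 genes, with 353 missing values among their extracts.

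Every contrast was fitted with limma 3.58.1 (lmFit and eBayes, two-sided moderated test) in R 4.3.3, with all 12 extracts in 1 model and the experiment as a block, which leaves 6 residual degrees of freedom. This model leaves out which extracts shared an array. siDNMT1 shared arrays with siGFP in every experiment, siMAD in experiment 1 alone and sipRb in none, so the contrasts with siGFP are not alike in this. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was the threshold. The experiment numbers pair the extracts: in the 18 pairs of extracts from the same experiment, deviations from the siRNA means correlated at r from 0.638 to 0.900, against -0.768 to 0.423 between experiments, and the first principal component held 62.8% of the variance, 98.5% of it between experiments. The pairing also follows from the labels, which number the experiments. The labels do not say whether the cultures of an experiment were grown separately beyond that, so the p-values measure the spread between these extracts, part of which may be technical.

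The contrasts, the model, 27 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Named are each siRNA's target, the 8 largest rises and 8 largest falls past the threshold that went the same way in all 3 experiments of a contrast with siGFP, up to 4 members of each described list (those past the threshold with the largest change first, otherwise those with the largest change), and the 3 largest rises and falls of each contrast between depletions. Any gene named outside this rule is said to have been chosen after its values were seen. Lists were tested with camera, with its preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 27 lists. Members were also counted after adjustment over the list alone. With the estimated correlation, 0 of the 27 lists passed in any of the 6 contrasts.

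The procedure was tested on data simulated on this design for siMAD against siGFP over 11577 genes. Of 100 genes changed by log2 1, 74% were recovered, and of 100 changed by log2 2, 99%, with 0 of the wrong sign. Among 180 calls 7 were false. A list of 40 genes shifted by log2 0.5 was called, and 0 of 26 unshifted lists were. Genes were simulated as independent of each other, each with the same spread in all extracts. The simulation therefore cannot tell how often a list whose members vary together is called without a shift. For comparisons against the shared control, unchanged groups were simulated 100 times against the same control extracts.

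Alternatives were quantile normalization, a shift by the median, the series table, no filter on dim probes or a stricter one, the mean of a gene's probes, no block, each dye alone, other treatments of the dye and of the samples, only the groups compared in the fit, an intensity trend with a robust prior, other thresholds, and each experiment and each extract left out. Extract weights, a fit of every kept probe, the mean of the 3 depletions and simulations with each extract's own spread were chosen after seeing the data. Tables and figures were made with the data.table package (version 1.17.8), jsonlite 2.0.0, Python 3.11.15 and matplotlib 3.10.9.

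The precision of each value is limited by the number of arrays. The share of probes well above background was 63.4% to 77.6% in the 8 samples of experiment 1, 59.1% to 66.3% in the 8 of experiment 2 and 37.4% to 61.5% in the 6 of experiment 3. No spot was saturated. Genomic positions are not given.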

Results

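IMR-90 lung fibroblasts were depleted of DNMT1, the enzyme that maintains DNA methylation after replication, of MAD2, a protein of the spindle checkpoint, or of pRb, the retinoblastoma protein that restrains the E2F transcription factors. The series asks whether cells made aneuploid by these 3 depletions share a molecular signature. Each siRNA and the siGFP control was profiled in 3 experiments. The labels name no other siRNA to the same target, so effects of losing a target cannot be told apart from other effects of its siRNA. This gave 5 samples for siGFP, 5 for siMAD, 6 for siDNMT1 and 6 for sipRb, from 3 extracts per siRNA (n = 3 in every comparison). Values are log2 processed signals relative to each sample's 75th percentile, and 12357 genes were tested. The 75th percentile signal was 817 to 1250 in experiment 1, 548 to 761 in experiment 2 and 510 to 517 in experiment 3. The siGFP extract of experiment 3 was measured in 1 sample, in which 37.4% of probes were well above background, the lowest share of the 22 samples.

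Each siRNA lowered its target in all 3 experiments. DNMT1 (Entrez gene 1786) had a mean log2 level of -2.15 ± 0.77 (SD, n = 3) after siDNMT1 and -0.27 ± 0.69 after siGFP, a log2 fold change of -1.88 (SE 0.31) that left 27.2% of the control level. Its changes were -1.99, -1.51 and -2.13 in experiments 1, 2 and 3, and the size of the last is uncertain, since DNMT1 was not well above background in the Cy5 sample of siDNMT1 there (a level of -2.17, against -1.5 in Cy3). MAD2L1 (Entrez gene 4085), which encodes MAD2, went from 0.07 ± 0.34 in siGFP to -2.41 ± 0.99 in siMAD, a change of -2.49 (SE 0.29) that left 17.8%. Within the 3 experiments it changed by -3.28, -1.82 and -2.36. RB1 (Entrez gene 5925), which encodes pRb, went from 1.69 ± 0.21 to -0.36 ± 0.41 after sipRb, a change of -2.04 (SE 0.27) that left 24.3%, and by -2.72, -1.88 and -1.53 within the experiments. Adjusted over the 3 targets, limma gave adjusted p = 0.000101 for DNMT1, 1.15e-05 for MAD2L1 and 1.93e-05 for RB1. Adjusted over all genes, MAD2L1 passed the threshold (adjusted p = 0.0115), while RB1 (0.0759) and DNMT1 (0.25) did not. A second, dimmer RB1 probe gave -1.04. The MAD2L1 call was lost without the siGFP extract of experiment 2 (adjusted p = 0.0525) or the siMAD extract of experiment 3 (0.0948), RB1 passed without the siMAD extract of experiment 1 (0.0294), and DNMT1 passed without the sipRb extract of experiment 1 (0.0354).

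**Figure D1:**
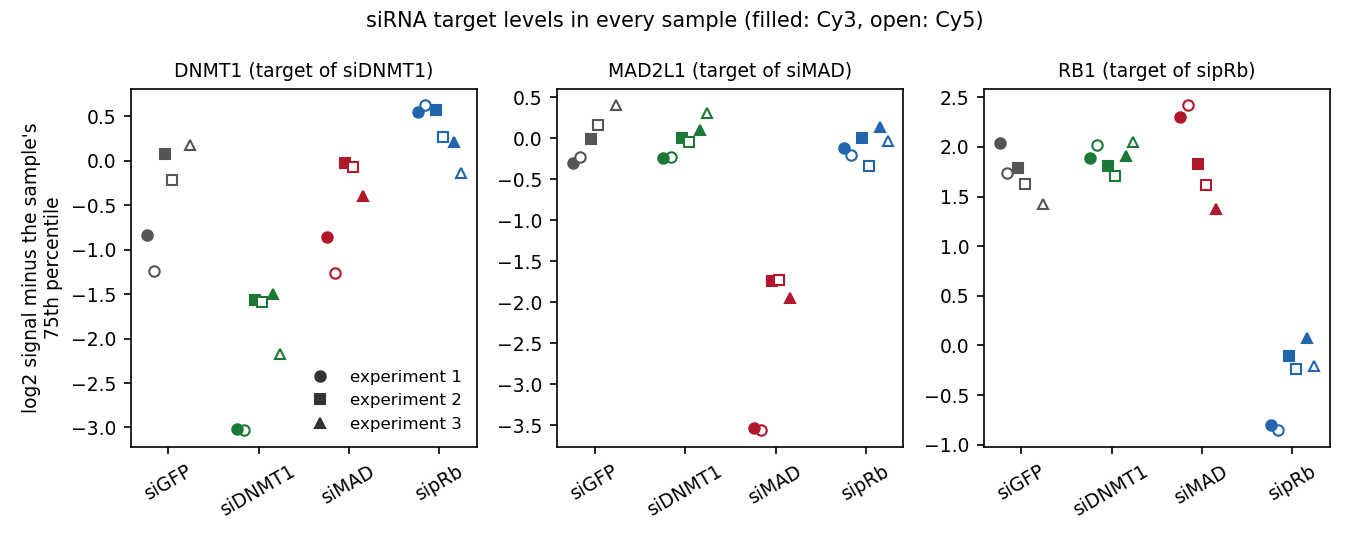
Log2 signal of DNMT1, MAD2L1 and RB1 minus each sample's 75th percentile (vertical axes), in every sample of the 4 siRNAs, with the shape giving the experiment and the fill giving the dye. Within each experiment the target lies lower after its own siRNA than in siGFP, with log2 differences from -2.13 to -1.51 for DNMT1, -3.28 to -1.82 for MAD2L1 and -2.72 to -1.53 for RB1.

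Depletion of DNMT1 was compared with siGFP to find the genes that differ after the siRNA to this methyltransferase. As a set, the senescence-associated secretory genes, the cytokines and proteases that senescent fibroblasts release, fell after siDNMT1 (camera adjusted p = 0.000671; adjusted p = 0.911 with an estimated correlation). Of 38 measured members 33 were lower, with a median log2 fold change of -0.32 and medians of -0.27, -0.28 and -0.25 in experiments 1, 2 and 3. The stromelysin MMP10 fell by 1.45 on the log2 scale (SE 0.28; adjusted p = 0.0137 over the list alone, 0.636 over all genes), the only member to pass over the list alone. CXCL8, the neutrophil chemokine interleukin-8, had a log2 fold change of -1.13, the chemokine CCL7 -0.81 and the secreted glycoprotein STC1 -0.78. Interferon response genes, the antiviral genes induced through STAT transcription factors, were called higher as a set, with 30 of 37 above 0 and a median of 0.28 (camera adjusted p = 0.00526; adjusted p = 0.911 with an estimated correlation). That call rests on experiment 1, where the median was 1.28, against -0.31 and -0.12 in experiments 2 and 3. HERC6 had 1.33, IFI27 1.10, MX1 1.02 and IFI6 0.95, and 0 members passed after adjustment over the list alone. The number of secretory members past the threshold over the list alone, 1, was 0 without the siDNMT1 extract of experiment 1 and 3 without the siGFP extract of experiment 1, and that of interferon members was 1 without siGFP of experiment 2.

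Smaller shifts after siDNMT1 were called in 4 more lists, each with an adjusted p of 0.911 with an estimated correlation and 0 members past the threshold over the list alone. Replication-dependent histone genes, the histones made in S phase, had 29 of 33 members lower, with a median of -0.16 (camera adjusted p = 0.00952). Among them H4C4 had -0.62, H1-2 -0.53, H2AC20 -0.49 and H2AC8 -0.48, and these near-identical family members may not be told apart by their probes. Hypoxia and glycolysis genes had 25 of 28 members lower, with a median of -0.17 (camera adjusted p = 0.0205), among them the vasodilator peptide ADM at -0.53, the growth factor VEGFA at -0.46, the glycolytic regulator PFKFB3 at -0.43 and the glucose transporter SLC2A1 at -0.40. Mitosis and G2/M genes had a median of -0.16 with 42 of 50 lower (camera adjusted p = 0.0057; 0.03, -0.11 and -0.44 in the 3 experiments), and NRF2 and oxidative stress genes a median of -0.12 with 18 of 24 lower (camera adjusted p = 0.0446). Germline genes that promoter methylation normally silences had 7 of 58 members bright enough to test, with a median of 0.08 (camera adjusted p = 0.686), and 22 imprinted genes had a median of -0.10 (camera adjusted p = 0.607), which a shift by the median turned to 0.05.

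Of 12357 genes, 0 passed the threshold in siDNMT1 against siGFP with limma, and 825 had an unadjusted p under 0.05 (370 higher and 455 lower). About 618 would have such a p if no gene had changed. The smallest adjusted p, 0.157, belonged to JAZF1, a zinc finger cofactor with a log2 fold change of -1.11 (SE 0.16), and was shared by MZT1, a component of microtubule-nucleating complexes, at -1.05 (SE 0.15). Both were chosen after their values were seen. The secretory call was lost without the siDNMT1 extract of experiment 1 (median -0.10, adjusted p = 0.26) and moved to -0.20 without the siGFP extract of experiment 3. The interferon median turned without the siGFP extract of experiment 1 (-0.25, adjusted p = 0.00167), missed the threshold without siDNMT1 of experiment 1 (0.32, 0.054), and was 0.72 and 0.60 without siGFP of experiments 2 and 3. With extract weights, chosen after seeing the data, it was 0.02 and the call was lost (adjusted p = 0.944).

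The smaller lists depended on single extracts as well. The mitosis call was lost without siGFP of experiments 2 (median -0.11, adjusted p = 0.356) or 3 (-0.07, 0.0593) and without siDNMT1 of experiments 1 (-0.17, 0.0642) or 3 (-0.09, 0.404), and its median was -0.30 without siGFP of experiment 1 and -0.26 without siDNMT1 of experiment 2. The histone call was lost without siGFP of experiment 2 (-0.12, 0.147) or siDNMT1 of experiment 1 (-0.07, 0.403), and its median was -0.07 without siGFP of experiment 3 and -0.25 without siDNMT1 of experiment 3. The hypoxia call was lost without siGFP of experiments 2 (-0.17, 0.198) or 3 (-0.10, 0.0601) and without siDNMT1 of experiments 1 (-0.22, 0.054) or 2 (-0.12, 0.0501), and its median was -0.31 without siGFP of experiment 1. The NRF2 call was lost without siGFP of experiments 1 (-0.19, 0.186) or 2 (-0.13, 0.198), siDNMT1 of experiment 1 (0.02, 0.724) or sipRb of experiment 2 (-0.12, 0.0522), and its median was -0.26 without siDNMT1 of experiment 3. Sizes and member counts in this contrast depended on the scaling. A shift by the median moved the median of all genes from -0.03 to 0.12. It left histone genes a median of -0.01 with 17 of 33 lower, hypoxia genes -0.02 with 14 of 28, mitosis genes -0.02 with 27 of 50, NRF2 genes -0.06 with 13 of 24 and secretory genes -0.20 with 25 of 38, while the interferon median was 0.43. Relative to the median of all genes, the histone, hypoxia and mitosis medians were -0.14, -0.15 and -0.14 as reported and -0.13, -0.14 and -0.14 after that shift, and these 3 calls held. Processing choices ended calls as well. The NRF2 call was lost with a shift by the median (-0.06, 0.0543), the series table (-0.07, 0.127), probes well above background in every sample (-0.12, 0.0595), the mean of a gene's probes (-0.10, 0.0783), a plain average of the dyes (-0.11, 0.0686), Cy3 or Cy5 alone (-0.12, 0.102, and -0.17, 0.0749) and extract weights, chosen after seeing the data (-0.10, 0.0562). The hypoxia call was lost with Cy3 or Cy5 alone (-0.15, 0.141, and -0.13, 0.128), the histone call with Cy3 alone (-0.08, 0.223) and the mitosis call with Cy5 alone (-0.18, 0.0749).

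Depletion of MAD2 was compared with siGFP to find the genes that differ after the siRNA to this checkpoint protein. In siMAD, 92 genes passed the threshold, 24 higher and 68 lower, 90 of them in the same direction in all 3 experiments and 66 by at least 2-fold. After MAD2L1 itself, the largest falls were TXNIP, an arrestin-fold protein that restrains glucose uptake, at -2.30 (SE 0.22; adjusted p = 0.00683), and ISCA2, a mitochondrial iron-sulfur cluster assembly factor, at -2.27 (SE 0.23; adjusted p = 0.00683). MPC2, a subunit of the mitochondrial pyruvate carrier, fell by 2.08 and ARRDC4, an arrestin-domain relative of TXNIP, by 1.83. The phosphatidylcholine transfer protein gene PCTP fell by 1.77, the kinase gene UHMK1 by 1.77 and the G protein subunit gene GNG10 by 1.68, with adjusted p from 0.0115 to 0.0414 over these 5 genes. The largest rise was KRT34, a hair keratin at 1.92 (SE 0.28; adjusted p = 0.0202), whose probe may also report near-identical keratins. It was followed by C2CD2 at 1.74 and MIR17HG, the host transcript of a microRNA cluster, at 1.69. Each was well above background in 5 of 5 siMAD samples. In siGFP this held in 3 of 5 samples for KRT34, 4 of 5 for C2CD2 and 2 of 5 for MIR17HG, which leaves the sizes of these changes uncertain. AGT, which encodes angiotensinogen, rose by 1.69, the imprinted gene NAP1L5 at 1.68, the teneurin TENM4 at 1.62, the matrix protease MMP3 at 1.52 and the antisense transcript UNC5B-AS1 at 1.5. The adjusted p of the 7 genes after KRT34 ranged from 0.0115 to 0.0344. The count of 92 genes was 15, 0 and 28 without the siGFP extract of experiments 1, 2 and 3, 13, 44 and 0 without siMAD, 56, 20 and 20 without siDNMT1, and 20 and 27 without the sipRb extract of experiments 2 and 3. Of the 15 named genes other than MAD2L1, 0 passed without siGFP of experiment 2 or siMAD of experiment 3, 6 to 15 passed without any other extract, and 0 turned their sign. Only 10 of these 15 could be tested when probes had to be well above background in every sample, and these 10 passed. The count was 0 with no filter on dim probes, with the Cy5 samples alone or with only these groups in the fit, and a shift by the median, which moved the median of all genes from -0.05 to 0.08, gave 36 genes, 18 higher and 18 lower.

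**Figure D2:**
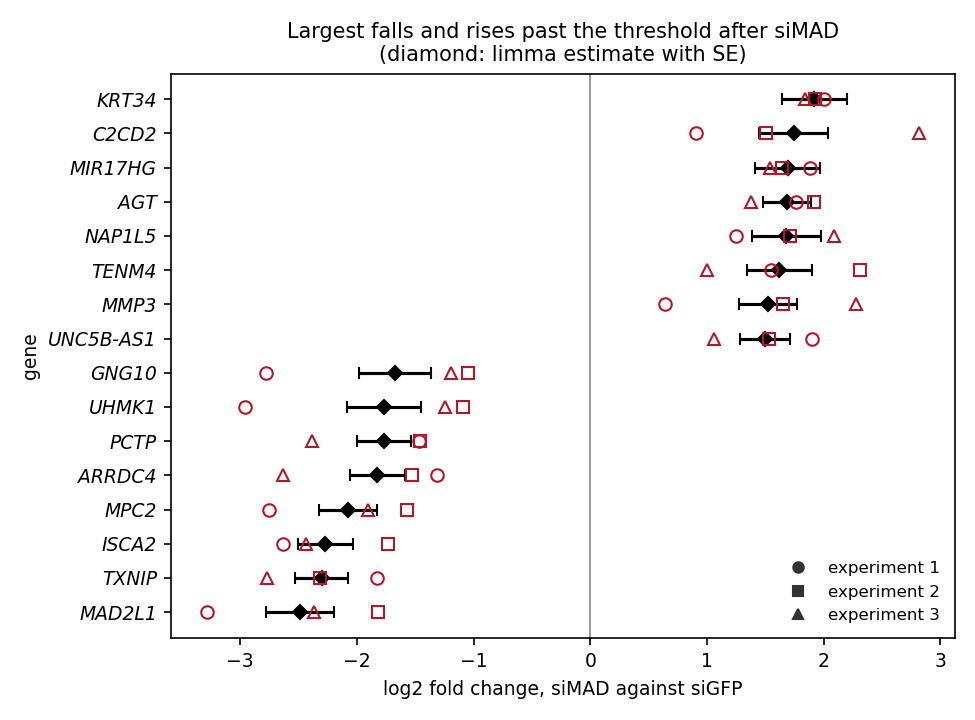
Log2 fold change, siMAD against siGFP (horizontal axis), of the 8 largest rises and 8 largest falls past the threshold: diamonds with bars are the limma estimate with its SE, and open symbols are the difference within each experiment. Only genes that went the same way in all 3 experiments were eligible, so all 16 lie on 1 side of 0 by selection. The estimates run from -2.49 for MAD2L1 to 1.92 for KRT34.

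Cell division genes fell as a group after siMAD. Of 50 measured mitosis and G2/M genes, 49 were lower, with a median of -0.50 (camera adjusted p = 5.87e-12; adjusted p = 0.756 with an estimated correlation). The medians were -0.36, -0.59 and -0.68 in experiments 1, 2 and 3. The cyclin gene CCNB2 fell by 0.79 (adjusted p = 0.0319 over all genes). Adjusted over the list alone, 19 members fell, among them AURKB, the kinase of the chromosomal passenger complex, at -0.98 (adjusted p = 0.017) and SPC24, a kinetochore subunit, at -0.92 (0.0108). The condensin subunit NCAPH at -1.16 (0.0707) did not pass. Spindle checkpoint and kinetochore genes, which share members such as AURKB with that list, had 35 of 41 members lower and a median of -0.29 (camera adjusted p = 8.05e-05; adjusted p = 0.828 with an estimated correlation). ZWILCH, part of the complex that brings checkpoint proteins to kinetochores, fell by 1.09 (adjusted p = 0.0162 over all genes). In all, 11 members fell when adjusted over the list alone, among them CENPH at -1.16 (adjusted p = 0.049). The 19 mitosis members past the threshold over the list alone became 4 without siGFP of experiment 2 or 3 or siMAD of experiment 2, and 7 without siMAD of experiment 1 or 3. The 11 spindle members became 4 to 7 without siGFP of experiments 2 or 3, any 1 siMAD extract, siDNMT1 of experiment 2 or sipRb of experiment 3.

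Cholesterol biosynthesis genes rose as a group after siMAD, with 23 of 25 above 0 and a median of 0.46 (camera adjusted p = 7.23e-08; adjusted p = 0.756 with an estimated correlation). The medians were 0.80, 0.42 and -0.15 in experiments 1, 2 and 3. Over all genes 0 members passed, and 5 rose when adjusted over the list alone. Among them were the sterol transporter STARD4 at 1.02 (adjusted p = 0.017), HMGCS1, which makes the precursor HMG-CoA, at 0.97 (0.0264), and the sterol demethylation enzymes NSDHL at 0.82 (0.0164) and MSMO1 at 0.81 (0.0151). Senescence-associated secretory genes had 30 of 38 members above 0 and a median of 0.33 (camera adjusted p = 8.05e-05; adjusted p = 0.828 with an estimated correlation), and with 0.57, 0.07 and -0.04 in the 3 experiments. MMP3 and the chemokine CXCL5 (1.2, adjusted p = 0.0297) rose over all genes, and 5 members rose when adjusted over the list alone. The chemokines CXCL1 at 2.49 (SE 1.5) and CCL20 at 2.31 (SE 0.98) did not pass. CXCL1 differed by 6.48 in experiment 1 and by 0.18 in experiment 2. Genes induced by p53, the tumour suppressor that answers DNA damage, had 23 of 36 members above 0 and a median of 0.19 (camera adjusted p = 0.00396; adjusted p = 0.828 with an estimated correlation). Over all genes 0 passed and 9 rose when adjusted over the list alone. Among these were the inositol phosphatase INPP5D at 2.0 (adjusted p = 0.0163), the mitochondrial quality control gene SPATA18 at 1.23 (0.0232), the stress cytokine GDF15 at 1.19 (0.00808) and SESN1, a sestrin, at 1.06 (0.0107). Hypoxia and glycolysis genes had a median of 0.18 with 20 of 28 above 0 (camera adjusted p = 0.00319; adjusted p = 0.756 with an estimated correlation). The glucose transporter SLC2A3 rose by 1.10 (adjusted p = 0.0469), the histone demethylase KDM3A rose by 0.70 when adjusted over the list alone (adjusted p = 0.0445), and NDRG1 at 0.59 and BNIP3 at 0.39 did not pass. Counts over the list alone moved with single extracts. The 5 cholesterol members became 1 without siGFP of experiment 1, 11 without siGFP of experiment 3 and 9 without siMAD of experiment 3, and the 9 p53 members became 4 without siGFP of experiment 1 and 2 without siMAD of experiment 1. The 5 secretory members became 2 without siMAD of experiment 1, 3 without siGFP of experiments 2 or 3, siMAD of experiment 3 or sipRb of experiments 2 or 3, and 8 without sipRb of experiment 1. The 2 hypoxia members became 0 without siMAD of experiments 1 or 3 and 1 without siGFP or siDNMT1 of experiments 1 or 2 or sipRb of experiments 2 or 3.

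In other lists single members moved without the list as a whole. DICER1, the endonuclease that matures microRNAs, fell by 1.51 after siMAD (adjusted p = 0.0291), and over the list of RNA interference genes alone the silencing factors TNRC6B at -1.46 and TARBP2 at -0.58 fell and TNRC6A at 0.59 rose (adjusted p = 0.0398 each). The 14 genes of that list had a median of -0.07 (camera adjusted p = 0.619), which a shift by the median turned to 0.07. Among unfolded protein response genes, the amino acid synthesis genes ASNS (-1.24, adjusted p = 0.0319) and, over the list alone, PSAT1 (-0.95, adjusted p = 0.008) fell, the chaperone gene HYOU1 (0.91, adjusted p = 0.0119) rose over the list alone. HSPA5 at 0.92 did not pass, with a list median of 0.03 and a mean of -0.00 (camera adjusted p = 0.619 in the upward direction). With no filter on dim probes the unfolded protein list was called in that direction (median 0.03, camera adjusted p = 0.035). The mitosis, spindle and cholesterol calls held without any 1 extract, although the cholesterol median was 0.19 without the siGFP extract of experiment 1. The secretory call was lost without the siMAD extract of experiment 1 (median 0.03, adjusted p = 0.231), the hypoxia call without the siGFP extract of experiment 1 (0.10, 0.134; without that of experiment 2 the median was 0.11), and the p53 call with probes well above background in every sample (0.17, 0.0637). With a shift by the median the spindle median was -0.15 with 30 of 41 lower, the hypoxia median 0.32 and the p53 median 0.31. With quantile normalization the hypoxia median was 0.10, or 0.14 relative to the median of all genes, against 0.23 relative to it as reported. The 4 RNA interference members that passed over the list alone became 1 or 2 without 7 of the 12 extracts, which were siGFP of experiments 1 and 2, siDNMT1 of experiment 3, siMAD of experiments 1 and 3 and sipRb of experiments 2 and 3. The 5 unfolded protein response members became 2 without siGFP of experiment 3 or siMAD of experiments 1 or 3, and 3 without siDNMT1 of experiment 2.

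**Figure D3:**
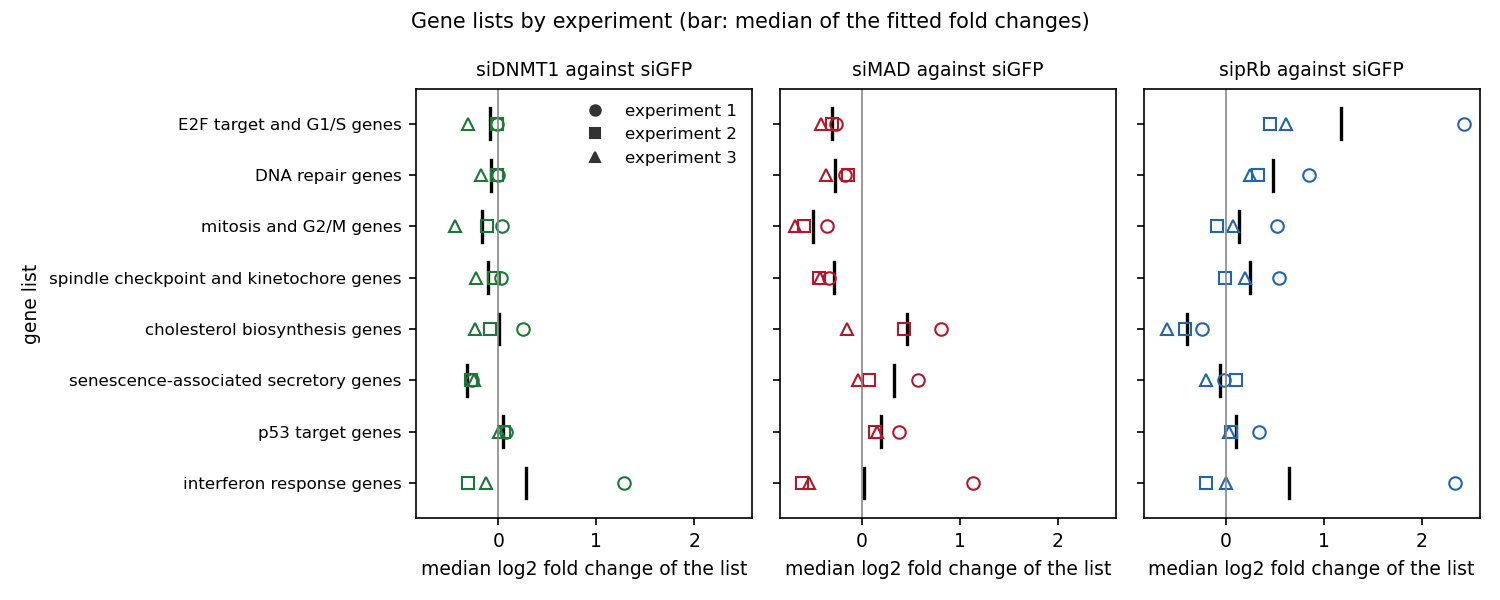
Median log2 fold change against siGFP (horizontal axes) of 8 gene lists (vertical axis) after siDNMT1, siMAD and sipRb: open symbols are medians within each experiment and bars are medians of the limma estimates. The E2F list lies at 2.44, 0.45 and 0.61 after sipRb, and the mitosis list at -0.36, -0.59 and -0.68 after siMAD.

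Depletion of pRb was compared with siGFP to find the genes that differ after its siRNA. E2F target and G1/S genes, which drive entry into DNA replication, rose as a group, with 41 of 42 members above 0 and a median of 1.17 (camera adjusted p = 1.61e-23; adjusted p = 0.45 with an estimated correlation). The medians were 2.44 in experiment 1, 0.45 in experiment 2 and 0.61 in experiment 3. Over all genes 0 members of any list passed in this contrast, and counts of members are adjusted over the list alone. Of the E2F list 32 members rose, among them the chromatin remodeller HELLS at 2.25 (SE 0.44; adjusted p = 0.00514), the primase subunit PRIM1 at 2.14 (SE 0.47; 0.00774), the chromatin assembly factor subunit CHAF1B at 1.98 (SE 0.51; 0.0107). DTL, which targets replication licensing factors for degradation, rose by 1.77 (SE 0.62; adjusted p = 0.0266). DNA repair genes had 31 of 41 members above 0 and a median of 0.48 (camera adjusted p = 1.18e-09; adjusted p = 0.45 with an estimated correlation). Over the list alone 12 rose, among them the Fanconi anaemia genes FANCL at 1.64 (adjusted p = 0.0127) and FANCI at 1.30 (0.0127) and the BRCA2 partner PALB2 at 1.55 (0.0159). RAD54L at 1.26 (0.0574) did not pass. The 32 E2F members became 11 without siGFP of experiment 1 and 20 without sipRb of experiment 1, and the 12 DNA repair members became 1 and 7 without these, 6 without siGFP of experiment 2 and 19 without sipRb of experiment 2.

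Cholesterol biosynthesis genes fell after sipRb, with 23 of 25 members below 0 and a median of -0.39 (camera adjusted p = 2.95e-05; adjusted p = 0.626 with an estimated correlation). The medians were -0.24, -0.42 and -0.60 in the 3 experiments. Over the list alone 8 fell, among them HMGCS1 at -1.04 (adjusted p = 0.0214), MSMO1 at -1.04 (0.00302), DHCR7, the last enzyme of the pathway, at -0.88 (0.0171) and HSD17B7 at -0.79 (0.0214). Autophagy and lysosome genes had 29 of 37 members below 0 and a median of -0.17 (camera adjusted p = 0.00171; adjusted p = 0.234 with an estimated correlation). Over the list alone 4 fell, among them the autophagosome proteins GABARAPL1 at -1.04 (adjusted p = 0.0419) and GABARAPL2 at -0.63 (0.0419) and the lysosomal channel MCOLN1 at -0.69 (0.0442). The protease CTSS at -1.04 (0.0943) did not pass. NRF2 and oxidative stress genes had 22 of 24 members below 0 and a median of -0.21 (camera adjusted p = 0.00567; adjusted p = 0.45 with an estimated correlation). ME1 at -0.74 (adjusted p = 0.0334) and OSGIN1 at -0.59 (0.0385) fell over the list alone, and the haem oxygenase HMOX1 at -0.81 (0.0589) and NQO1 at -0.64 (0.0565) did not pass. Replication-dependent histone genes had 25 of 33 members below 0 and a median of -0.25 (camera adjusted p = 0.0128; adjusted p = 0.742 with an estimated correlation). Over the list alone 5 fell, among them H2AC6 at -1.11 (adjusted p = 0.00166), H2AC8 at -0.90, H1-2 at -0.82 and H2AC20 at -0.77 (adjusted p = 0.0215 each), again uncertain between near-identical family members. These counts over the list alone were unstable. The 8 cholesterol members became 2 without siGFP of experiment 2 and 1 without siGFP of experiment 3 or sipRb of experiments 1 or 3. The 5 histone members became 1 without siGFP of experiments 2 or 3 or any 1 sipRb extract. The 4 autophagy members became 1 without siGFP of experiment 2, 2 without sipRb of experiment 2, 4 without siMAD of experiments 1 or 3 and 0 without any other extract. The 2 NRF2 members became 1 without siGFP of experiment 1, 2 without siDNMT1 of experiment 2, 3 without siMAD of experiment 3, 4 without siDNMT1 or siMAD of experiment 1 and 0 without any other extract.

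Interferon response genes had 34 of 37 members above 0 after sipRb and a median of 0.64 (camera adjusted p = 5.35e-07; adjusted p = 0.742 with an estimated correlation), with 2.34 in experiment 1, -0.20 in experiment 2 and 0.00 in experiment 3. MX1 had 2.27 (SE 0.88), HERC6 1.91, IFI44 1.57 and OAS3 1.45, and 0 members passed over the list alone. Spindle checkpoint and kinetochore genes had 31 of 41 above 0 and a median of 0.25 (camera adjusted p = 4.28e-05; adjusted p = 0.626 with an estimated correlation). Over the list alone KNTC1 at 1.46 (adjusted p = 0.00674) and DSN1 at 1.30 (0.0338) rose and 1 other member fell. CENPK at 1.24 and CENPU at 1.15 did not pass. Genes induced by p53 had a median of 0.10 with 25 of 36 above 0 (camera adjusted p = 0.0152; adjusted p = 0.742 with an estimated correlation). Over the list alone 5 rose, among them INPP5D at 2.55 (adjusted p = 0.0243), SPATA18 at 1.34 (0.042) and the damage-binding gene DDB2 at 0.90 (0.042). GDF15 at 0.74 (0.0895) did not pass. DNA methylation and heterochromatin regulators had a median of 0.04 with 23 of 32 above 0 (camera adjusted p = 0.0362; adjusted p = 0.742 with an estimated correlation). HELLS and the heterochromatin protein CBX5 at 1.06 (adjusted p = 0.0157) rose over the list alone, and the methyltransferases EZH2 at 1.6 (0.0997) and DNMT1 at 0.62 did not pass. Mitosis and G2/M genes had a median of 0.13 with 38 of 50 above 0 (camera adjusted p = 0.00567; adjusted p = 0.816 with an estimated correlation). Of the interferon list 14 members passed over the list alone without siGFP of experiment 2, 8 spindle members and 1 mitosis member without sipRb of experiment 2, and the 5 p53 members became 0 to 3 without 10 of the 12 extracts, all but siGFP and siDNMT1 of experiment 3. The 2 DNA methylation members became 0 without siGFP of experiment 3, 1 without siGFP of experiment 2 or sipRb of experiment 1 and 4 without sipRb of experiment 2.

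Gene by gene, 0 of 12357 passed the threshold in sipRb against siGFP with limma, 2183 had an unadjusted p under 0.05 (960 higher and 1223 lower), and the smallest adjusted p was 0.0759, shared by RB1 and other genes. The E2F, DNA repair, cholesterol and autophagy calls held without any 1 extract. Their medians were 0.52 for E2F and 0.29 for DNA repair genes without the sipRb extract of experiment 1, -0.22 for cholesterol without siGFP of experiment 3 and -0.27 for autophagy without siGFP of experiment 2. Without the siGFP extract of experiment 1, calls were lost for interferon (median -0.02, adjusted p = 0.682), mitosis (0.06, 0.612), p53 (0.06, 0.127) and DNA methylation genes (0.03, 0.463). Without the sipRb extract of experiment 1 they were lost for mitosis (0.06, 0.409), p53 (0.03, 0.342) and DNA methylation genes (0.02, 0.25), while the medians were 0.24 for interferon and 0.11 for spindle genes. The same held for NRF2 genes without sipRb of experiment 2 (-0.22, 0.0727), for histone genes without siGFP or sipRb of experiment 2 (-0.15, 0.0516, and -0.19, 0.0825), and for DNA methylation genes without siGFP of experiment 2 (0.01, 0.0559) or siMAD of experiment 1 (0.04, 0.0593). Medians also moved to 1.0 for interferon without siGFP of experiment 2, to 0.38 for spindle and 0.22 for mitosis genes without sipRb of experiment 2, and to 0.17 for p53 and 0.13 for DNA methylation genes without sipRb of experiment 3. Without siGFP of experiment 3 they were 0.24 for mitosis, -0.15 for histone and 0.17 for DNA methylation genes. Without all of experiment 1, the spindle call was lost (0.09, 0.128) and the interferon median was -0.19. A shift by the median moved the median of all genes from -0.06 to 0.05 and the medians to -0.07 for autophagy (25 of 37 below 0), -0.14 for NRF2 and -0.14 for histone genes, 0.24 for mitosis, 0.19 for p53 and 0.16 for DNA methylation genes. Relative to the median of all genes the autophagy median was -0.12 under both scalings. With extract weights, chosen after seeing the data, calls were lost for interferon (0.18, 0.423), spindle (0.15, 0.0605), mitosis (0.11, 0.421), p53 (0.06, 0.291) and DNA methylation genes (0.08, 0.0884). Probes well above background in every sample ended the p53 and DNA methylation calls (0.08 and 0.04, 0.0559 each) and Cy5 alone the histone call (-0.20, 0.0779). The DNA methylation call was also lost with quantile normalization (0.04, 0.0753), the series table (0.12, 0.0547) and Cy5 alone (0.09, 0.0593).

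**Figure D4:**
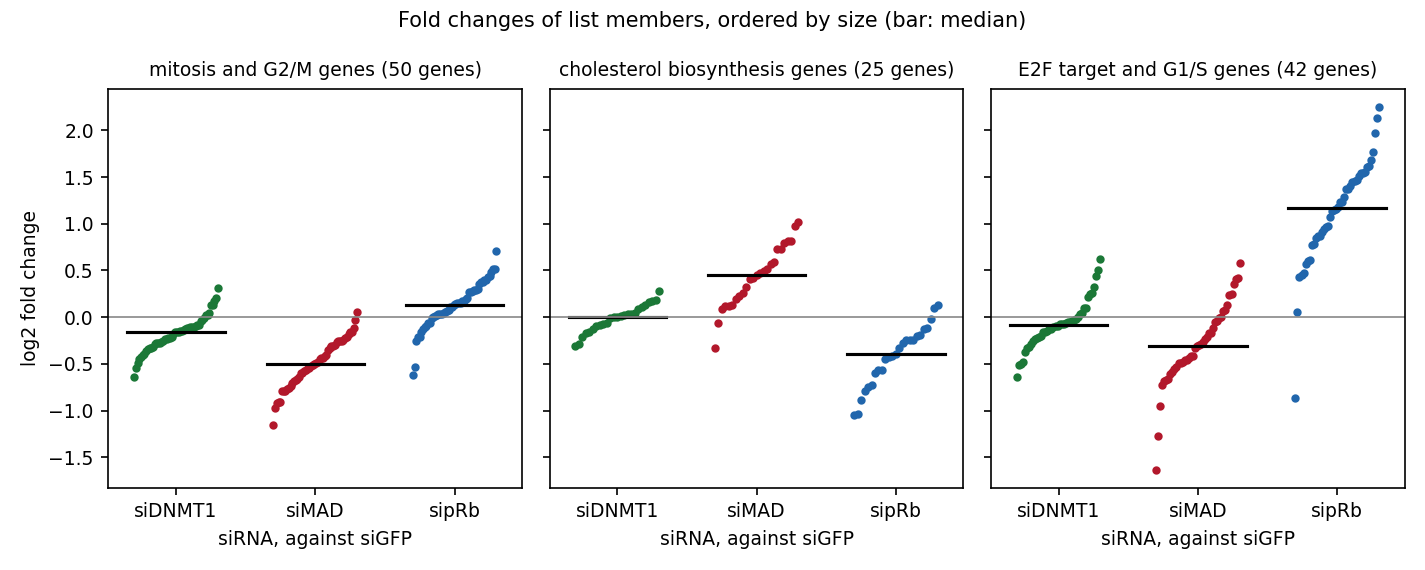
Log2 fold change against siGFP (vertical axis) of each measured member of 3 gene lists after siDNMT1, siMAD and sipRb, ordered by size, with bars at the medians. The cholesterol list has medians of 0.46 after siMAD and -0.39 after sipRb, and the E2F list 1.17 after sipRb.

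To look for the shared signature, the 3 contrasts with siGFP were set side by side. With limma, 0 genes passed the adjusted threshold in the same direction in all 3 depletions, and at an unadjusted p under 0.05, 48 genes were higher and 36 lower in all 3. Unchanged groups were simulated with a shared control that was itself simulated, so the measured siGFP values were not held fixed. These groups gave means of 27.1 genes higher (17 to 43 over 100 simulations) and 27.9 lower (15 to 42), and independent lists of these sizes would share 1.84 and 4.55 genes. Of 12035 genes with all differences measured, 530 had the same sign in all 9 differences within experiments, 186 higher and 344 lower. The shared siGFP extracts make such agreement common, and the simulated groups gave 188 higher (152 to 222) and 186 lower (158 to 219). The observed higher count lay within that range and the lower count above it. Simulated genes were independent of each other, so all these ranges are too narrow for genes that vary together. They therefore cannot tell whether the lower count is an excess. Simulated changes were centred on 0, while the median of all genes was -0.03, -0.05 and -0.06 after siDNMT1, siMAD and sipRb. A shift by the median turned these to 0.12, 0.08 and 0.05. The counts were not repeated with that shift, so an effect of scaling on the lower count was not tested. The 3 contrasts had 1 sign in 46.4% of genes, against 49.1% to 51.2% in the simulated groups and a mean of 57.6% when each simulated extract had its own spread. The genes that follow were chosen after their values were seen, for a small p in the limma test of the mean of the 3 depletions against siGFP. That test does not ask for a change in each depletion. RIDA, a mitochondrial deaminase of reactive intermediates, was at -0.78, -1.07 and -1.01 after siDNMT1, siMAD and sipRb. ITGB8, an integrin subunit, had -1.04, -0.84 and -0.69. The hyaluronan synthase HAS2 had 0.39, 1.15 and 1.48, and the prostaglandin receptor PTGFR 0.55, 1.26 and 0.73. Tested as the mean of the 3 depletions against siGFP, 0 genes passed, 1459 had an unadjusted p under 0.05, and the smallest adjusted p was 0.309, for RIDA at -0.95 (SE 0.14).

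Fold changes of the depletions against siGFP correlated across 12035 genes, which are not independent replicates, at r = 0.40 for siDNMT1 and siMAD, 0.40 for siDNMT1 and sipRb and 0.35 for siMAD and sipRb. Unchanged groups that shared a simulated control gave 0.499, 0.499 and 0.502. The covariances were 0.0393, 0.0414 and 0.0481, against simulated values of 0.0246, 0.0245 and 0.0247, and against 0.0349, 0.0349 and 0.035 when each simulated extract had its own spread. With 3 control extracts the controls could not be split, and part of the excess may come from them. Without siGFP of experiment 1 the correlation of siDNMT1 and siMAD was 0.60, without siGFP of experiment 3 it was 0.25 and without siMAD of experiment 3 it was 0.26. That of siMAD and sipRb was 0.23 without either its siMAD or its sipRb extract of experiment 3. Without all of experiment 3 the 3 correlations were 0.15, 0.25 and 0.20, and without all of experiment 1 that of siMAD and sipRb was 0.62.

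The depletions were also compared with each other, without the shared control. Between siMAD and sipRb 368 genes passed, 132 higher and 236 lower in siMAD, all in the same direction in the 3 experiments. The chemokine gene PF4V1, uncertain against its near-identical relative, was higher by 2.81 (SE 0.65; adjusted p = 0.0483), and KRT34 by 2.49 (0.00961). LBP, which encodes the lipopolysaccharide-binding protein, was at least 4.37-fold higher in siMAD (adjusted p = 0.0127), being well above background in 5 of 5 siMAD samples and 0 of 6 sipRb samples. Lower in siMAD were the ribonucleotide reductase subunit RRM2 at -2.61 (SE 0.58; adjusted p = 0.043), PRIM1 at -2.47 (0.0331) and CHAF1B at -2.44 (0.0381). As lists, E2F target genes were lower in siMAD than in sipRb in 42 of 42 members, with a median of -1.44 (camera adjusted p = 1.24e-23; adjusted p = 0.255 with an estimated correlation). Of them 17 passed over all genes and 38 when adjusted over the list alone. Each of the following had an adjusted p of 0.167 with an estimated correlation. Mitosis genes had a median of -0.62 (13 lower over all genes, 32 over the list alone, camera adjusted p = 9.86e-18), spindle genes -0.67 (11 lower and 1 higher over all genes, 28 and 1 over the list alone, 1.58e-12) and DNA repair genes -0.75 (12 lower, 22 over the list alone, 2.02e-12). Cholesterol genes were higher in siMAD with a median of 0.88 (10 higher, 20 over the list alone, 4.95e-15), with 1.07, 0.87 and 0.61 in the 3 experiments. The count of 368 was 105 without the siGFP extract of experiment 2 and 710 without that of experiment 3, 89, 53 and 81 without siDNMT1 of experiments 1, 2 and 3, 21, 143 and 0 without siMAD, and 52, 240 and 37 without sipRb. Without the sipRb extract of experiment 1, RRM2 was at -1.71 and did not pass (adjusted p = 0.116), PRIM1 was at -1.64 and CHAF1B at -1.53, and the E2F median was -0.89. Without the siMAD extract of experiment 1 PF4V1 was at 1.67 and did not pass (adjusted p = 0.0944). These 4 genes lay close to the threshold, and without 1 extract their adjusted p reached 0.184 for RRM2, 0.159 for PRIM1, 0.181 for CHAF1B and 0.183 for PF4V1, with the same sign throughout. The 32 mitosis members that passed over the list alone became 18 without siMAD of experiment 2 and 15 and 21 without sipRb of experiments 1 and 3, and the 29 spindle members became 16 without sipRb of experiment 1.

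Between siDNMT1 and siMAD 165 genes passed, 98 higher and 67 lower in siDNMT1, 164 of them in the same direction in all experiments. Higher in siDNMT1 were MAD2L1 by 2.40 (SE 0.29; adjusted p = 0.0122), MPC2 by 2.37 (0.00862) and the membrane protein gene TMEM9B by 2.14 (0.019). Lower were the metalloprotease ADAM12 at -2.29 (0.0165), LBP at -2.24 (0.0207; well above background in 2 of 6 siDNMT1 samples, which leaves its size uncertain) and the chemokine CXCL12 at -1.97 (0.0125). Secretory genes were lower in siDNMT1 than in siMAD with a median of -0.64 (4 past the threshold over all genes and 10 adjusted over the list alone, camera adjusted p = 5.63e-12; adjusted p = 0.311 with an estimated correlation). So were cholesterol genes at -0.39 (1 and 7, 6.34e-08; adjusted p = 0.442 with an estimated correlation) and hypoxia genes at -0.30 (0 and 4, 6.34e-08; adjusted p = 0.311 with an estimated correlation). Mitosis genes were higher with a median of 0.36 in 47 of 50 members (0 past the threshold over the list alone, camera adjusted p = 5.49e-07; adjusted p = 0.648 with an estimated correlation). The count of 165 was 279 without the siGFP extract of experiment 3, 5, 11 and 0 without siDNMT1 of experiments 1, 2 and 3, 8, 91 and 0 without siMAD, and 100 without sipRb of experiment 2. The 10 secretory members that passed over the list alone became 17 without siGFP of experiment 3 or siMAD of experiment 2 and 5 without siDNMT1 of experiment 1, and the 7 cholesterol members became 2 and 1 without siDNMT1 of experiments 2 and 3 and 4 without siMAD of experiment 1. The 4 hypoxia members became 0 without siGFP of experiment 2, any 1 siDNMT1 extract or siMAD of experiments 1 or 2, and 7 without siGFP or sipRb of experiment 1. Of the mitosis list 2 members passed without siGFP of experiment 3 and 1 without siMAD of experiment 3 or sipRb of experiments 1 or 2.

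Between siDNMT1 and sipRb 3 genes passed, which were RB1, higher by 2.25 in siDNMT1, DNMT1 at -2.50, and FZD8, a Wnt receptor, at -1.52 (adjusted p = 0.0328 each). E2F target genes were lower in siDNMT1 than in sipRb with a median of -1.23 (0 members over all genes and 34 adjusted over the list alone, camera adjusted p = 2.13e-24; adjusted p = 0.567 with an estimated correlation), as were DNA repair genes at -0.53 (0 and 13, 1.68e-10; adjusted p = 0.567 with an estimated correlation). Cholesterol genes were higher at 0.41 (0 and 9, 1e-05; adjusted p = 0.601 with an estimated correlation). The count of 3 was 0 without any 1 of the siGFP or siDNMT1 extracts, siMAD of experiments 2 or 3 or sipRb of experiment 2, and 13 without siMAD of experiment 1. Without sipRb of experiment 1 the E2F median was -0.61 and the DNA repair median -0.33. The 34 E2F members that passed over the list alone became 15 without siDNMT1 of experiment 1, and the 13 DNA repair members became 0 and 2 without siDNMT1 of experiments 1 and 3 and 6 without sipRb of experiment 1. The 9 cholesterol members became 0 without siDNMT1 of experiments 1 or 3 or sipRb of experiment 3, 1 without siMAD of experiment 2 or sipRb of experiment 1 and 5 without siDNMT1 or sipRb of experiment 2.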

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

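The tests of the interferon, E2F and covariance patterns below, and the splits of siDNMT1 against siGFP, sipRb against siGFP and the shared genes, were chosen only after the result was seen.

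Between depletions, compared directly with camera, secretory genes differed by a median log2 of -0.64 and hypoxia genes by -0.30 in siDNMT1 against siMAD (adjusted p = 0.311 each with an estimated correlation). Mitosis genes differed by -0.28 in siDNMT1 against sipRb (adjusted p = 0.601 with an estimated correlation). In siMAD against sipRb mitosis genes differed by -0.62, cholesterol genes by 0.88 and spindle genes by -0.67 (adjusted p = 0.167 each with an estimated correlation).

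A single sample lay far from the others of its siRNA in 3 of 152 groups of values tested. Chance alone would mark about 1 in 20 groups, or 7.6 here, if the samples of a group were independent. The 2 labellings of an extract are not, so an outlying extract with both dyes can go unmarked. MIR17HG had a log2 level of -4.73 in the Cy5 sample of sipRb in experiment 3, against -3.30 to -2.51 in the other 5. NAP1L5 had -0.63 in the Cy3 sample of sipRb in experiment 3, against 0.23 to 0.66 in the other 5. The median log2 level of secretory genes was 3.66 in the Cy3 sample of siMAD in experiment 3, against 3.19 to 3.27 in the other 4.

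Interferon response genes were higher than siGFP in experiment 1 in all 3 depletions. A single labelling or array is argued against by both dyes, with a lowest list median of 1.22 over the siDNMT1 and sipRb values. In siMAD the list median against siGFP was 1.13, which a low siGFP extract or a rise in all depletions would both give. Relative to each gene's mean, the list lay at -0.70 in siGFP of experiment 1, against -0.01 and 0.06 in experiments 2 and 3. In siDNMT1, siMAD and sipRb it lay at 0.72, 0.84 and 1.52 in experiment 1, against -0.72 to -0.08 in their other extracts. A low siGFP extract may account for part, but levels also differ between experiments as a whole. As the whole of the sipRb difference, a low siGFP extract is argued against by siMAD against sipRb, where the median was -0.87 with 31 of 37 members below 0. An effect of the siRNAs in that experiment alone stays open and was not tested.

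E2F target genes were higher after sipRb by more in experiment 1 than in experiments 2 and 3. A single labelling is argued against by the dyes, the lower of which gave a median of 2.41. For signal compressed across all genes in experiments 2 and 3, the 3 siRNA targets were compared. Their log2 fold changes there were 55.3% of those in experiment 1 or more (SD of the 6 percentages 18.8), against 18.7% and 25.2% for this list. The targets thus shrank less than the list. How far each siRNA worked may also differ between experiments, so the targets cannot settle whether signal was compressed. A lower level of the list in the other extracts of experiment 1 may account for part, since over siGFP, siDNMT1 and siMAD the list lay at -0.59 relative to experiments 2 and 3, below all of 10000 random lists (lowest -0.52). As the whole it is argued against by the sipRb extracts themselves, in which the list was higher in experiment 1 by 1.29 (highest random list 0.63). The random lists were matched in mean level alone and hold unrelated genes. They cannot tell how unusual such shifts are for a list whose members vary together. RB1 itself was lowered furthest in experiment 1, with 15.2% of the siGFP level left, against 27.2% and 34.6% in experiments 2 and 3. A deeper depletion of pRb or a stronger response to it in experiment 1 stays open as a hypothesis and was not tested.

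Fold changes of the 3 depletions varied together in experiment 3, where their covariances were 0.278 to 0.325. A response common to the depletions as the source is argued against by experiments 1 and 2, where the highest covariance was 0.0632. The spread of the siGFP extract of experiment 3, measured in 1 dim sample, may be the source. The SD over genes of its difference from siGFP in experiments 1 and 2 was 0.89, or 1.22 times the highest of the 3 depletions taken likewise, against ratios of 1.03 and 0.999 when experiments 1 and 2 were set against the others. A response present in experiment 3 alone stays open.

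The 6 extracts of each contrast make 10 splits, the real one included, too few for a share under 0.05. The highest count in any other split was 0 in each contrast. That includes the other splits that part all 3 pairs of extracts from the same experiment, which number 4 with the real one. The real counts were 92 (siMAD against siGFP), 165 (siDNMT1 against siMAD), 3 (siDNMT1 against sipRb) and 368 (siMAD against sipRb), each reached by 1 split of the 10, the real one. For siDNMT1 against siGFP and sipRb against siGFP the real count was 0, so all 10 splits were as large. For genes shared by the 3 depletions, all 100 groupings of the 12 extracts gave at least the real count of 0, and the highest gave 3.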

How the results depend on the processing

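Extract weights, the fit of every kept probe, the mean of the 3 depletions and the simulation with each extract's own spread were chosen after seeing the data. Normexp background correction was not run, since the files lack its columns. In what follows the counts stand in the order siMAD against siGFP (92 as reported), siDNMT1 against siMAD (165), siMAD against sipRb (368) and siDNMT1 against sipRb (3), and the cause was not tested unless given. Quantile normalization left 117 genes in siMAD against sipRb (46 higher, 71 lower) and 0 in siDNMT1 against sipRb. A shift by the median gave 36 (18 higher, 18 lower), 108, 180 (76 higher, 104 lower) and 1. The series table gave 33 (14 higher, 19 lower) in the first, 136 (65 higher, 71 lower) in siMAD against sipRb and 0 in siDNMT1 against sipRb, against 24 higher and 68 lower, and 132 higher and 236 lower, as reported. No filter on dim probes gave 0 in all 4 contrasts, and MAD2L1 at -2.49 (adjusted p = 0.118). Probes well above background in every sample, fewer genes, gave 250, 260 and, in siDNMT1 against sipRb, 63, with 3 in siDNMT1 against siGFP, 15 in sipRb against siGFP, RB1 past the threshold at -2.04 (adjusted p = 0.022) and no value for DNMT1. The mean of a gene's probes gave 57 in siMAD against siGFP and 0 in siDNMT1 against sipRb. Without the experiment as a block, so without the pairing, all 4 counts were 0 and MAD2L1 at -2.49 had an adjusted p of 0.367.

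The Cy3 samples alone, fewer samples, gave 14 in siMAD against siGFP, 9 in siDNMT1 against sipRb, 1 each in siDNMT1 and sipRb against siGFP and 1 shared gene. The Cy5 samples alone gave 0, 0, 0 and 1, and MAD2L1 at -2.64 (adjusted p = 0.0954). All samples kept separate, which counts both labellings of an extract as replicates, gave 1496, 1819, 3475 and 3059, with 277 in siDNMT1 and 1977 in sipRb against siGFP, 26 shared genes, and DNMT1 at -1.78 (adjusted p = 0.000165) and RB1 at -2.09 (2.25e-05) past the threshold. With only the groups compared in the fit, fewer samples, there were 0 in siMAD against siGFP, 18 in siMAD against sipRb and 0 in siDNMT1 against sipRb, and MAD2L1 at -2.49 (adjusted p = 0.164). An intensity trend with a robust prior gave 197, 254, 572 and 71, with 8 in sipRb against siGFP and RB1 past the threshold at -2.04 (adjusted p = 0.0259). Asking for at least 2-fold left 102 in siDNMT1 against siMAD and 204 in siMAD against sipRb, and an adjusted p under 0.01 left 2, 2, 3 and 0. Extract weights gave 209 (93 higher, 116 lower), 348, 132 (67 higher, 65 lower) and 48, with 1 in siDNMT1 and 22 in sipRb against siGFP and RB1 past the threshold at -1.94 (adjusted p = 0.0161). Every kept probe gave 0 in siDNMT1 against sipRb. Within experiments the targets moved most to -3.28 for MAD2L1 and -2.72 for RB1 in experiment 1 and -1.51 for DNMT1 in experiment 2.

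Without 1 experiment or extract at a time, fewer samples, the counts ran from 0 to 133 in siMAD against siGFP, 0 to 279 in siDNMT1 against siMAD, 0 to 710 in siMAD against sipRb, 0 to 13 in siDNMT1 against sipRb, 0 to 1 in siDNMT1 against siGFP, 0 to 2 in sipRb against siGFP and 0 to 0 for shared genes. The targets ran from -2.08 to -1.60 for DNMT1, -2.84 to -2.02 for MAD2L1 and -2.30 to -1.67 for RB1. The correlations of fold changes ran from 0.15 to 0.60 for siDNMT1 and siMAD, 0.25 to 0.60 for siDNMT1 and sipRb and 0.20 to 0.62 for siMAD and sipRb.

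Among the named genes, these signs reversed, and among the lists, these test directions. Without experiment 1, after siDNMT1 MX1 was at -0.43, IFI6 at -0.15 and the interferon median at -0.15, and after sipRb OAS3 at -0.35 and the interferon median at -0.19. Without the siGFP extract of experiment 1, IFI27 was at -0.25, MX1 at -0.56, IFI6 at -0.44 and the interferon median at -0.25 after siDNMT1, and OAS3 at -0.04 after sipRb. Without the siMAD extract of experiment 1, CXCL1 was at -0.40 and the unfolded protein median at -0.091 after siMAD. With the Cy3 samples alone the latter was -0.0031. With extract weights, MX1 was at -0.051 and the imprinted median at -0.048 after siDNMT1, where that median kept its sign while its test direction turned. With no filter the RNA interference median after siMAD, -0.065, also kept its sign while its test direction turned. The highest values of those results without 1 experiment or extract, against the reversed ones as the lowest, were 1.83 for IFI27, 2.10 for MX1, 1.71 for IFI6 and 0.72 for the interferon median after siDNMT1, 2.42 for OAS3 and 1.07 for the interferon median after sipRb, and 4.03 for CXCL1 and 0.15 for the unfolded protein median after siMAD.

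Apart from these, 19 list medians turned their sign while the direction of their test did not. After siDNMT1 the imprinted median was 0.051 with a shift by the median, the germline median -0.011 with the Cy3 samples alone and -0.020 with extract weights, and the NRF2 median 0.025 without siDNMT1 of experiment 1. After siMAD the RNA interference median was 0.071 with a shift by the median, 0.015 with the series table, 0.039 and 0.027 with the Cy3 and Cy5 samples alone and 0.040 with all samples separate. After sipRb the mitosis median was -0.030 and the DNA methylation median -0.016 without experiment 1, and the interferon median -0.018 without siGFP of experiment 1. The other 7 were medians of uncalled lists without 1 experiment or extract, from -0.037 to 0.079.

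Over all alternatives, the named genes kept direction and side of the threshold in 2639 comparisons, lost the threshold in 535, passed it in 79 and reversed in 9, and the lists, by the direction and threshold of their test, did so in 1057, 105, 1 and 7. Counts of members past the threshold over the list alone stayed within 1.5 times in 781 comparisons and moved in 350. They ran from 0 to 27 for mitosis after siMAD, 0 to 25 for DNA repair after sipRb and 0 to 14 for autophagy after sipRb. Of the lists described, 0 of 6 after siDNMT1, 3 of 6 after siMAD and 4 of 11 after sipRb kept their call under all 29 settings other than the estimated correlation. Signal over background limits the dimmest samples, those of experiment 3, where 37.4% of probes were well above background in the siGFP sample.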

Other observations

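The lists were fixed before the data were examined, and the values below, some of them on lists and genes also described in the report, were chosen for this part after the main results were seen.

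Of 27 lists, 14 were called in no depletion against siGFP, with a smallest adjusted p of 0.0537 for fibroblast marker genes after siMAD, where the median of 18 genes was -0.31 with 16 of them lower. COL3A1, a fibrillar collagen of that list and of the extracellular matrix list that was chosen after its value was seen, fell after siMAD by 0.99 on the log2 scale (adjusted p = 0.046), while the 51 matrix genes had a median of -0.09. The 61 ribosomal protein genes had medians of -0.02, -0.07 and -0.12 after siDNMT1, siMAD and sipRb. The 28 heat shock and chaperone genes had -0.02, -0.01 and -0.11, with a mean above 0 after siMAD. The 17 genes of MHC class I and antigen processing, which present peptides on the cell surface, had 0.15, -0.28 and -0.00 (test direction upward after sipRb), and the 29 contractile and TGF-beta response genes had -0.04, -0.07 and -0.14. Few marker genes of other cell types were bright enough to test, 7 endothelial, 9 epithelial and 6 leukocyte, and their medians after siMAD were -0.37, -0.05 (with a mean above 0) and 0.00.

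The siRNA targets were also measured in the depletions not aimed at them. DNMT1 had -0.27 after siMAD and 0.62 after sipRb, MAD2L1 had -0.09 after siDNMT1 and -0.17 after sipRb, and RB1 had 0.21 after siDNMT1 and 0.12 after siMAD.

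On 2 arrays of experiment 2 both channels carried the same siRNA, and their mean absolute log10 ratios were 0.0356 and 0.0368, against 0.0643 to 0.212 on the 9 arrays with different siRNAs. In the siGFP sample of experiment 3 the scanner software's linear dye normalization factor was 14.0, the highest of the 22 samples, and the lowest extract weight, 0.195, was that of its extract.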
